A study of Mus musculus with 12 samples.

How the data were processed

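Total RNA of mouse urinary bladder was measured on 12 cDNA arrays, 1 for each of 4 treatments (saline, ovalbumin, substance P and LPS) at 3 times (1, 4 and 24 h). The groups were taken from the sample titles. Each group holds 1 array, and the labels do not say how many mice gave its RNA, so the p-values measure only the spread between these arrays, part of which may be technical. The labels describe the ovalbumin mice as sensitized and do not say this of the other mice. They give the sex as female for all but the ovalbumin mice.

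The deposited table holds an intensity for each of 1185 probes on each array, on a linear scale. The scanner, the image software, the background step and the array type are not given in the sources used here. The values show neither background subtraction nor a common scale. None is 0 or below, the 10th percentile of an array lies at 68.4% to 94.1% of its median, and the highest array median is 3.6 times the lowest. Of the 12 columns, 11 hold whole numbers and the ovalbumin 1 h column holds decimals, for which the labels give no reason. The highest Spearman correlation between any 2 arrays was 0.89, so no array was treated as a copy of another.

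The table names its probes by codes in 3 series (597 M, 351 V and 237 MA codes) and does not pair them with genes. None of the codes equals a symbol, gene ID or accession in the reference gene table used here (assembly GRCm38.p6). A further 16 codes happen to equal a synonym of some gene, which was not used. The gene lists and cell type markers fixed in advance could therefore not be tested, and no gene is named. Probes are given by code, at most 2 in each direction for a comparison.

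The rule for choosing genes, fixed before the data were examined, named none from a probe without a gene, so it was applied here to probe codes and shortened after the data were seen. For each stimulus against saline it took the 2 highest and 2 lowest mean log2 ratios over the 3 times. These probes had to be above the floor on at least 4 arrays of the stimulus and saline and to have the same sign at all 3 times. For the other comparisons it took the 2 highest and 2 lowest fitted differences among probes past the threshold. The parts of the rule on extremes at each single time, on members of the gene lists and on housekeeping genes were not used.

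Arrays were put on one scale by quantile normalization (limma 3.58.1 in R 4.3.3). Values were then raised to a floor, the 10th percentile of all values (47684), and log2-transformed. The 1181 probes above the floor on at least 3 of 12 arrays were tested and 4 were left out. The background left in the intensities can alter the ratio of a dim probe between arrays, and a correction for it was run as an alternative.

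Single comparisons of 1 array with 1 array have no replicate check and carry no p-value. They are given as log2 ratios and as counts of probes at least 2-fold apart, among probes above the floor on at least 1 of the 2 arrays. The tests come from a limma model with stimulus and time as additive factors over all 12 arrays, which leaves 6 residual degrees of freedom (2.57 prior degrees of freedom, median residual SD 0.154 on the log2 scale). Its spread is array error together with any response that differs between times. The model therefore asks whether a shift averaged over the 3 times stands out, and a response at 1 time alone counts as error. The p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The SE given with a difference is the limma one, from the residual spread of all arrays in the fit. It is not the spread of the 3 against 3 arrays alone.

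The model was tested on simulated data with the real probe means and residual spreads, 20 sets of 1181 probes for ovalbumin against saline with 200 changed probes each. It called 71.7% of probes changed 1.5-fold, 91.4% of those changed 2-fold and 99.2% of those changed 4-fold, and 4.41% of its calls were unchanged probes. These shares are for a shift averaged over times, and a response at a single time counts as error in the model. Data built from probe means and residual spreads do not carry the likeness between real arrays, such as that of saline 24 h to ovalbumin. The shares therefore cannot show that a comparison without calls holds few 2-fold changes. The number of arrays limits the precision. The median half-width of the 95% interval of a stimulus-against-saline difference was 0.278 on the log2 scale.

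The labels give a lot and batch number pair for 6 arrays, and its first number was read as the lot. The 3 ovalbumin arrays have lot 1, and lot 2 is given for saline 1 h, saline 4 h and substance P 24 h. Stimulus, lot and sensitization cannot be told apart for ovalbumin.

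Alternatives fixed before the data were examined were median scaling, the deposited values without scaling, floors at the 5th and 25th percentiles, other filters, a trended robust variance, a fit without the second factor, array weights, and leaving out each array or time. Added after the data were seen were a normexp background correction (offset 50) before quantile normalization, and, for each stimulus against saline, a fit on the brighter probes only.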

Results

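The study profiled gene expression in the bladder of C57BL/6 mice after an inflammatory challenge. Ovalbumin stands for an antigen challenge: mice sensitized with DNP-HSA received DNP-OVA into the bladder. Substance P, a neuropeptide of sensory nerves, was given at 1 µM. LPS, a component of the outer membrane of Gram-negative bacteria, was given at 100 mg/ml as labelled. Saline was the control, and each treatment was sampled at 1, 4 and 24 h with 1 array per time. Array medians ran from 26283 intensity units (LPS 24 h) to 94600 (substance P 4 h). The 90th percentile was 3.52 times the 10th on the substance P 1 h array and 1.32 times on the ovalbumin 24 h array, so the arrays differed in usable range before scaling. Probe M567 was the brightest on all 12 arrays and took 3.39% to 18.1% of the summed intensity.

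**Figure D1:**
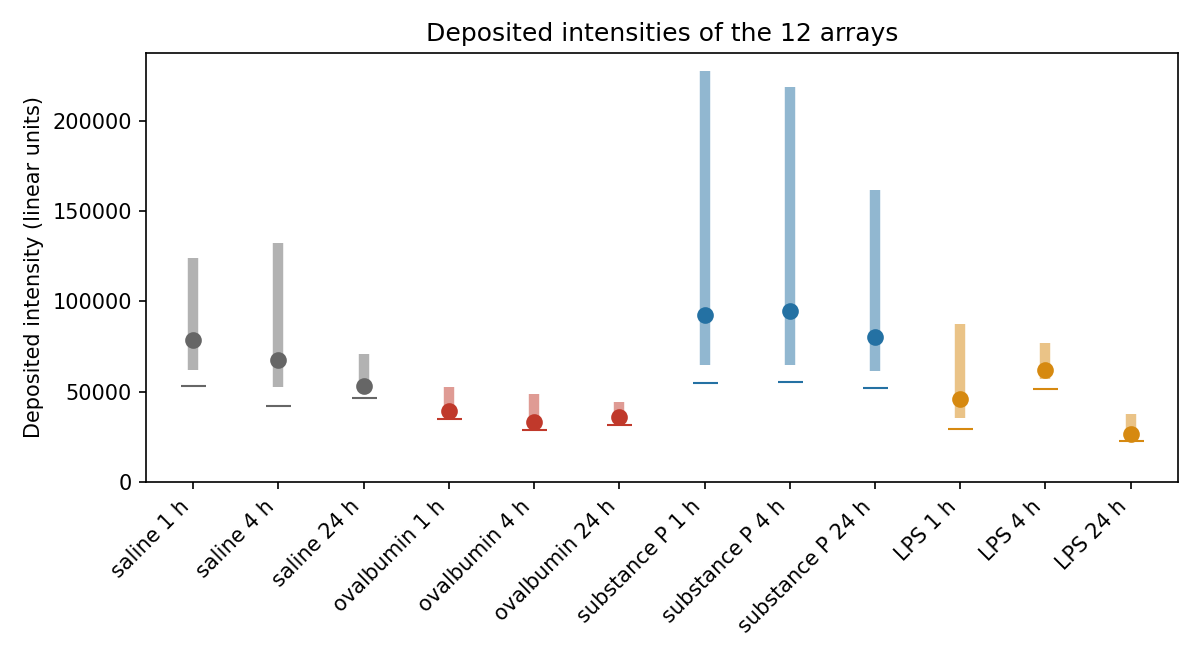
Deposited intensity (linear units) of the 12 arrays; dots are medians over 1185 probes, bars run from the 10th to the 90th percentile and dashes mark the dimmest probe. The substance P arrays have the widest range, and the ovalbumin arrays have medians between 33022 and 39336.

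The saline arrays give the background against which the stimuli are read. After quantile normalization, saline 1 h and saline 4 h had 8 probes at least 2-fold apart (r = 0.907 across probes). Saline 24 h differed from saline 1 h in 34 probes and from saline 4 h in 33. Saline 24 h was closer to the ovalbumin arrays, with a mean r of 0.934 against 0.841 with the other saline arrays, and its closest array was ovalbumin 1 h (r = 0.955). The mean r within a treatment was 0.929 for ovalbumin, 0.935 for substance P, 0.863 for saline and 0.804 for LPS. These correlations are across probes, which are not independent replicates.

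**Figure D2:**
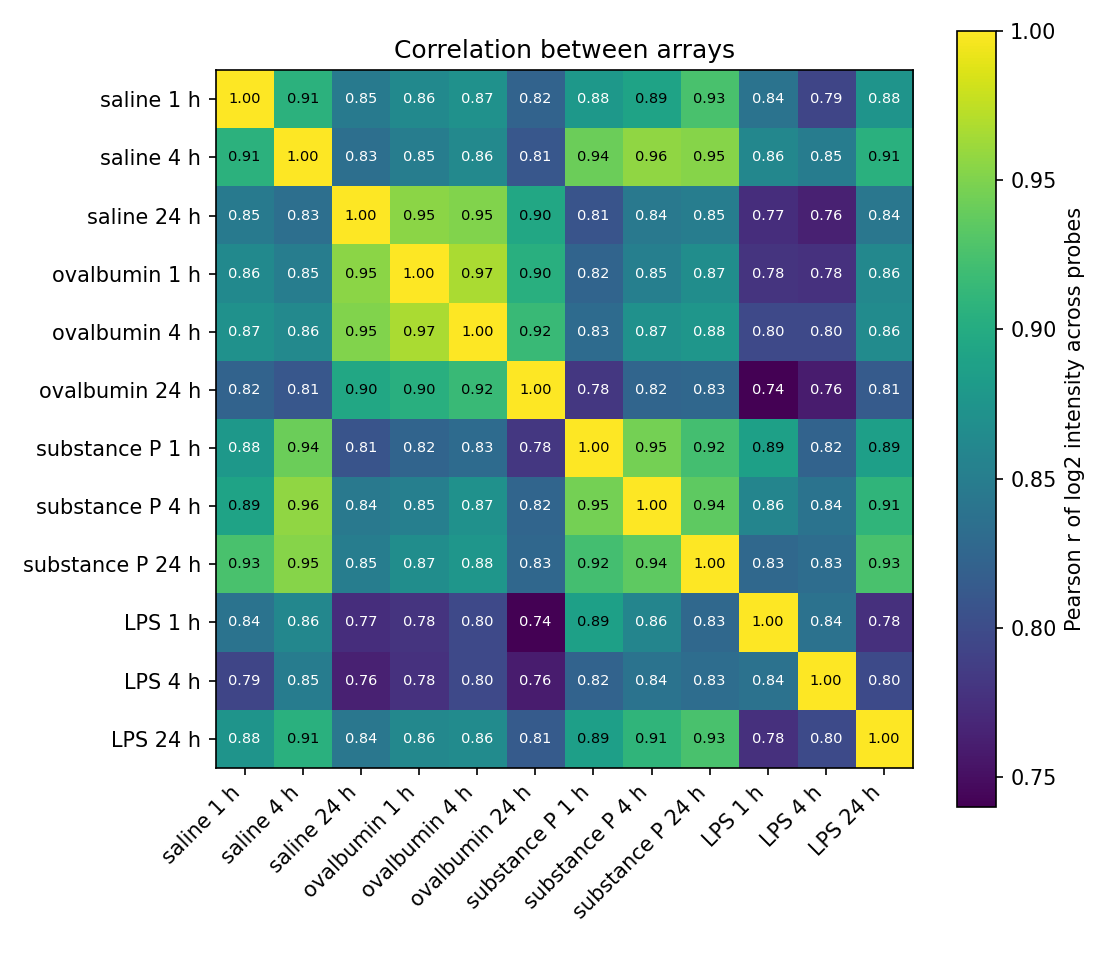
Pearson correlation of quantile-normalized log2 intensity across 1185 probes for each pair of the 12 arrays (colour and printed value). The saline 24 h row is highest in the ovalbumin columns.

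Ovalbumin against saline compared sensitized mice given antigen with saline mice, which the labels do not describe as sensitized. It cannot separate the challenge from the sensitization. Probe M779 was 3.18-fold lower than saline at 1 h and 3.83-fold lower at 4 h, but 1.02-fold lower at 24 h. Probe M205 was 2.08-fold, 2.60-fold and 1.20-fold lower at the same times. The highest mean ratios belonged to M134 and M722, both from the 24 h array. Without the ovalbumin 24 h array their log2 differences were 0.10 and 0.13. M134 was at 1.99 without ovalbumin 4 h, and M722 at 0.71 without saline 24 h. M134 was 13.4-fold above saline at 24 h and 1.16-fold and 1.01-fold above it at 1 h and 4 h, and M722 was 8.13-fold, 1.12-fold and 1.02-fold above it. M722 was at the floor on saline 24 h, so its 8.13-fold is a lower bound. M134 stood at or near the floor, at 15.54 to 15.86 on the log2 scale, on every array but ovalbumin 24 h. Without scaling, the averaged log2 difference of M722 turned to -0.26 and that of M134 was 0.12, while median scaling gave 0.61 for M722. Averaged over times, the log2 difference was -1.21 ± 0.38 (SE, 3 arrays against 3) for M779, -0.90 ± 0.27 for M205, 1.33 ± 0.73 for M134 and 1.07 ± 0.56 for M722. None of these passed the limma test, with adjusted p-values of 0.43, 0.407, 0.625 and 0.625. Without scaling M779 (-2.21) and M205 (-1.56) passed it. A normexp background correction, chosen after the data were seen, gave 2.55 for M134, 2.48 for M722 and -2.57 for M205, and none of these passed. Without all 24 h arrays M134 was at 0.12 and M722 at 0.09.

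No probe differed between ovalbumin and saline averaged over times in limma (lowest adjusted p = 0.0806), although 108 of 1181 had an unadjusted p under 0.05 where 59 would be expected by chance. Instead of 108 there were 73 under median scaling, 56 without saline 4 h, 67 without ovalbumin 1 h and 178 without saline 24 h. The number of probes past the adjusted threshold also depended on saline 24 h. Without that array 27 probes passed, 13 higher and 14 lower with ovalbumin, including M779 at -1.82 ± 0.16 (limma adjusted p = 0.00263) and M205 at -1.28 ± 0.19 (limma adjusted p = 0.0165). Without saline 4 h, M779 was at -0.80. On the saline 24 h array M779 stood at 16.53 on the log2 scale, beside 16.49 to 16.50 on the ovalbumin arrays and 18.15 and 18.43 on saline 1 h and 4 h. At single times, 10 probes were at least 2-fold higher and 13 lower at 1 h, 17 and 15 at 4 h, and 8 and 1 at 24 h. Median scaling changed these to 1 and 14, 2 and 42, and 2 and 7, and the deposited values gave 0 and 508, 0 and 540, and 2 and 43. In all, 150 probes lay above saline and 153 below it at all 3 times, 25.7% of those tested, where 25% would be expected by chance. With array weights 2 probes passed, and without scaling 1177, all lower. Because all ovalbumin arrays share lot 1 and only their mice are labelled as sensitized, challenge, sensitization and lot cannot be told apart here. No sex is given for the ovalbumin mice.

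Substance P against saline asked what the neuropeptide changes. The highest values were on the 1 h array: probe M781 was 11.9-fold above saline at 1 h, 1.87-fold at 4 h and 1.11-fold at 24 h, and probe M99 was 4.93-fold, 1.30-fold and 1.29-fold above it. The lowest mean ratios were those of V336 (1.24-fold, 1.23-fold and 2.19-fold below saline at 1, 4 and 24 h) and M668 (1.81-fold, 1.52-fold and 1.06-fold below). Averaged over times the log2 differences were 1.54 ± 0.80 (SE, 3 arrays against 3) for M781, 1.02 ± 0.47 for M99, -0.58 ± 0.31 for V336 and -0.51 ± 0.17 for M668. All 4 had a limma adjusted p of 0.871. Without scaling M781 (2.36) and M99 (1.91) passed the test, and M668 was at -0.13. After normexp correction M99 was at 1.66 and M668 at -1.54, and neither passed. Without all 1 h arrays M781 was at 0.53 and M99 at 0.37. M781 was at 0.79 without substance P 1 h and 0.95 without saline 1 h, and M99 at 0.48 without saline 1 h. Without saline 24 h, V336 was at -0.17 ± 0.23, and without all 24 h arrays at -0.30. Its direction reversed under median scaling (0.15) and without scaling (0.59).

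No probe passed the limma test for substance P averaged over times, and 52 of 1181 had an unadjusted p under 0.05. Instead of 52 there were 219 under median scaling, 126 without saline 4 h and 21 without substance P 1 h. Without scaling 343 passed the adjusted threshold, all higher. At 4 h, 3 probes were at least 2-fold higher and 1 lower, fewer than the 8 that separated saline 1 h from saline 4 h. At 1 h the counts were 12 higher and 2 lower, and at 24 h 18 and 13. The 24 h count rests on saline 24 h: the substance P 24 h array differed 2-fold from saline 24 h in 31 probes, from saline 1 h in 6 and from saline 4 h in 2, the last 2 comparisons being within lot 2. Under median scaling the counts were 72 and 0, 15 and 0, and 58 and 0, and without scaling 107 and 0, 75 and 0, and 208 and 0. The sign was the same at all 3 times for 27.3% of probes.

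LPS against saline asked what the bacterial product changes. Probe M781 was again highest, 11.9-fold above saline at 1 h, 2.89-fold at 4 h and 1.14-fold at 24 h, and V164 was 6.78-fold, 1.43-fold and 1.11-fold above it. Quantile normalization gives probes of equal rank the same value, so the 11.9-fold that M781 shares with substance P reflects an equal rank. Probe M318 was 1.29-fold, 3.41-fold and 2.72-fold below saline and V336 was 1.66-fold, 1.66-fold and 3.57-fold below it. Averaged over times the log2 differences were 1.76 ± 0.80 (SE, 3 arrays against 3) for M781, 1.14 ± 0.50 for V164, -1.19 ± 0.42 for M318 and -1.10 ± 0.31 for V336. Their limma adjusted p-values were 0.546, 0.53, 0.459 and 0.45. Without LPS 1 h, M781 was at 1.16 and V164 at 0.47, and without saline 1 h they were at 1.17 and 0.73. M318 was at -0.66 without LPS 4 h, and V336 at -0.69 ± 0.23 without saline 24 h. Without all 1 h arrays M781 was at 0.86 and V164 at 0.33, and without all 24 h arrays V336 was at -0.73. Median scaling gave 1.10 for M781. Without scaling M781 was at 0.52 and V164 at 0.23, and M318 (-1.73) and V336 (-1.46) passed the test. After normexp correction M318 was at -1.82 and V336 at -1.73, and neither passed.

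In limma, 0 probes passed for LPS averaged over times and 110 of 1181 had an unadjusted p under 0.05. Instead of 110 there were 56 under median scaling, 61 without LPS 4 h and 167 without LPS 24 h. Past the adjusted threshold, leaving out LPS 24 h gave 8 probes, 5 higher and 3 lower. Leaving out all 24 h arrays gave 2, and the unscaled values gave 437, all lower. The 1 h array had the most lopsided counts, with 30 probes at least 2-fold above saline and 3 below. The counts were 10 and 16 at 4 h, and 16 and 17 at 24 h. Median scaling gave 35 and 0 at 1 h, 0 and 76 at 4 h, and 14 and 5 at 24 h, and the deposited values 5 and 260, 0 and 93, and 1 and 114. The LPS 24 h array differed 2-fold from saline 4 h in 13 probes and from saline 24 h in 33. The normexp correction raised the counts at single times for all 3 stimuli to between 123 probes (substance P 4 h) and 451 (LPS 24 h), with 71 higher and 52 lower in the first and 216 and 235 in the second.

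**Figure D3:**
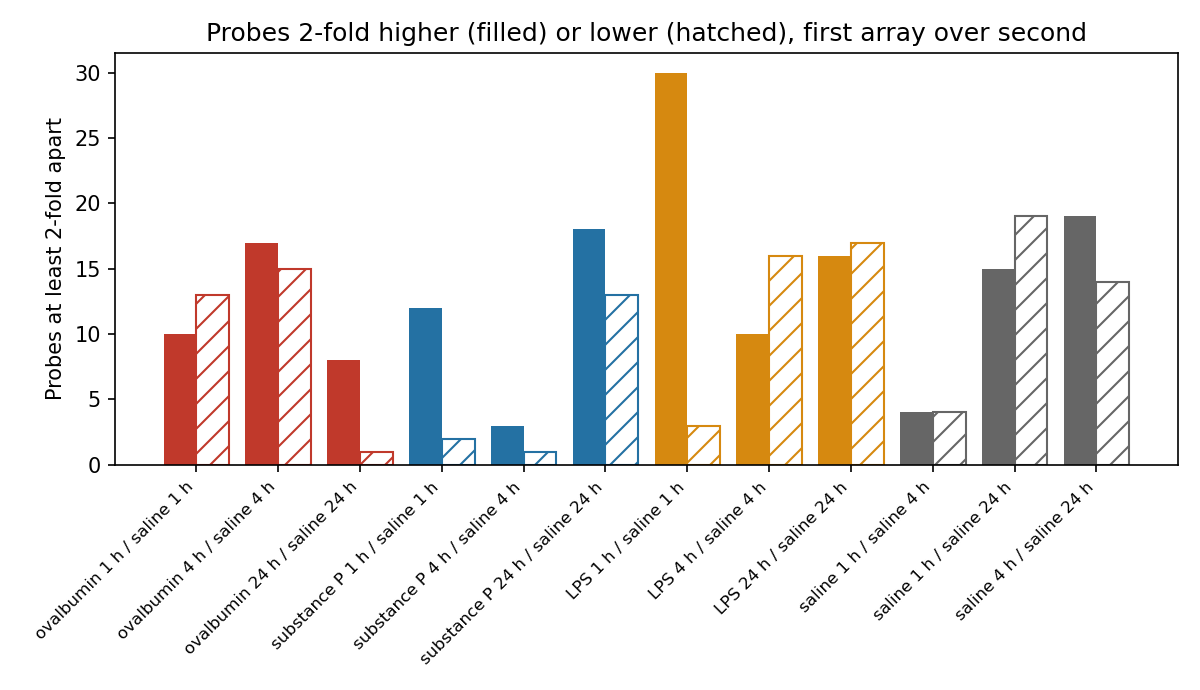
Number of probes at least 2-fold higher (filled bars) or lower (hatched bars) on the first array of each pair than on the second, after quantile normalization; each pair is 1 array against 1 array. The 3 grey pairs compare saline arrays, and the pairs with saline 24 h (34 and 33 probes) reach the highest total of any stimulus pair (33).

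The stimuli were then compared with each other, which does not use the saline levels. Ovalbumin and LPS differed in 34 probes averaged over times, 29 higher and 5 lower with ovalbumin (limma, adjusted p under the threshold). Probe M318 was higher with ovalbumin by 1.96 ± 0.42 on the log2 scale (3.90-fold, limma adjusted p = 0.0452) and V336 by 1.74 ± 0.31 (3.34-fold, limma adjusted p = 0.0243), each higher at 3 of 3 times. Probe M369 was lower by -1.33 ± 0.22 (2.52-fold, limma adjusted p = 0.0243) and M339 by -1.28 ± 0.25 (2.43-fold, limma adjusted p = 0.0323), each lower at 3 of 3 times. On the saline 24 h array M318 stood at 18.61 and V336 at 18.50, beside ovalbumin means of 18.93 and 18.23. When each of the 12 arrays was left out in turn, M318 passed in 1 of 12 fits (without saline 24 h), with a limma adjusted p from 0.0401 to 0.203 and a log2 difference from 1.43 to 2.46. V336 passed in 7 of these fits, M369 in 6 and M339 in 5, with the highest limma adjusted p at 0.134, 0.134 and 0.171. With the 25th percentile floor M318 had an adjusted p of 0.066 in limma, and under median scaling the adjusted p of these 4 probes ran from 0.749 to 0.799. Their log2 differences were then 1.29 for M318, 1.00 for V336, -1.06 for M369 and -0.89 for M339. Without scaling M318 was at 1.06 and V336 at 0.77 (limma adjusted p = 0.00288 and 0.071). After normexp correction M339 was at -2.19 (limma adjusted p = 0.0269), and without all 4 h arrays M318 was at 1.28 (limma adjusted p = 0.212).

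Ovalbumin and substance P differed in 6 probes, all higher with ovalbumin, and all 6 were also among those higher with ovalbumin than with LPS (0.147 expected for independent lists). Both comparisons use the ovalbumin arrays and the same residual spread for each probe. The lists are therefore not independent, and 0.147 is no fair reference for their overlap. Probe M665 was higher than with substance P by 1.22 ± 0.14 (2.33-fold) and M583 by 1.04 ± 0.11 (2.05-fold), both with a limma adjusted p of 0.00883 and higher at 3 of 3 times. Under median scaling M665 was at 0.15 (limma adjusted p = 0.481) and M583 at 0.59 (limma adjusted p = 0.0167), and after normexp correction M665 was at 1.77 (limma adjusted p = 0.0781) and M583 at 2.58 (limma adjusted p = 0.0395). Both reversed without scaling, to -1.15 and -0.72. There 1184 probes passed the threshold, all lower with ovalbumin, so this sign follows a shift of nearly all probes. With each array left out in turn, M665 passed in 6 of 12 fits and M583 in 7, with limma adjusted p-values from 0.000492 to 0.0937 and to 0.0891. In limma, 0 probes passed between substance P and LPS (66 with an unadjusted p under 0.05). Median scaling gave 33, all higher with substance P, the unscaled values 1152, all higher, and leaving out LPS 24 h gave 12.

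These counts depended on the scaling, the weighting and single arrays. With median scaling, ovalbumin against LPS gave 0 probes and ovalbumin against substance P gave 183, 20 higher and 163 lower, which held 1 of the 6. With array weights the second count was 201, 104 higher and 97 lower. Without scaling the counts were 30 (1 higher, 29 lower), which held 3 of the 34, and 1184 (all lower). Leaving out saline 24 h, which enters only through the spread and the time terms, gave 60 and 79 probes and included all 34 and all 6. For ovalbumin against LPS, 1 probe passed without ovalbumin 1 h, 2 without ovalbumin 4 h, LPS 1 h or LPS 4 h, 18 without LPS 24 h and 22 without substance P 1 h. Without all 1 h or all 4 h arrays 0 passed. For ovalbumin against substance P, 0 passed without any one of the ovalbumin arrays or without substance P 4 h or 24 h, 1 without substance P 1 h, 2 without saline 1 h or any one of the LPS arrays, and 25 without saline 4 h.

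**Figure D4:**
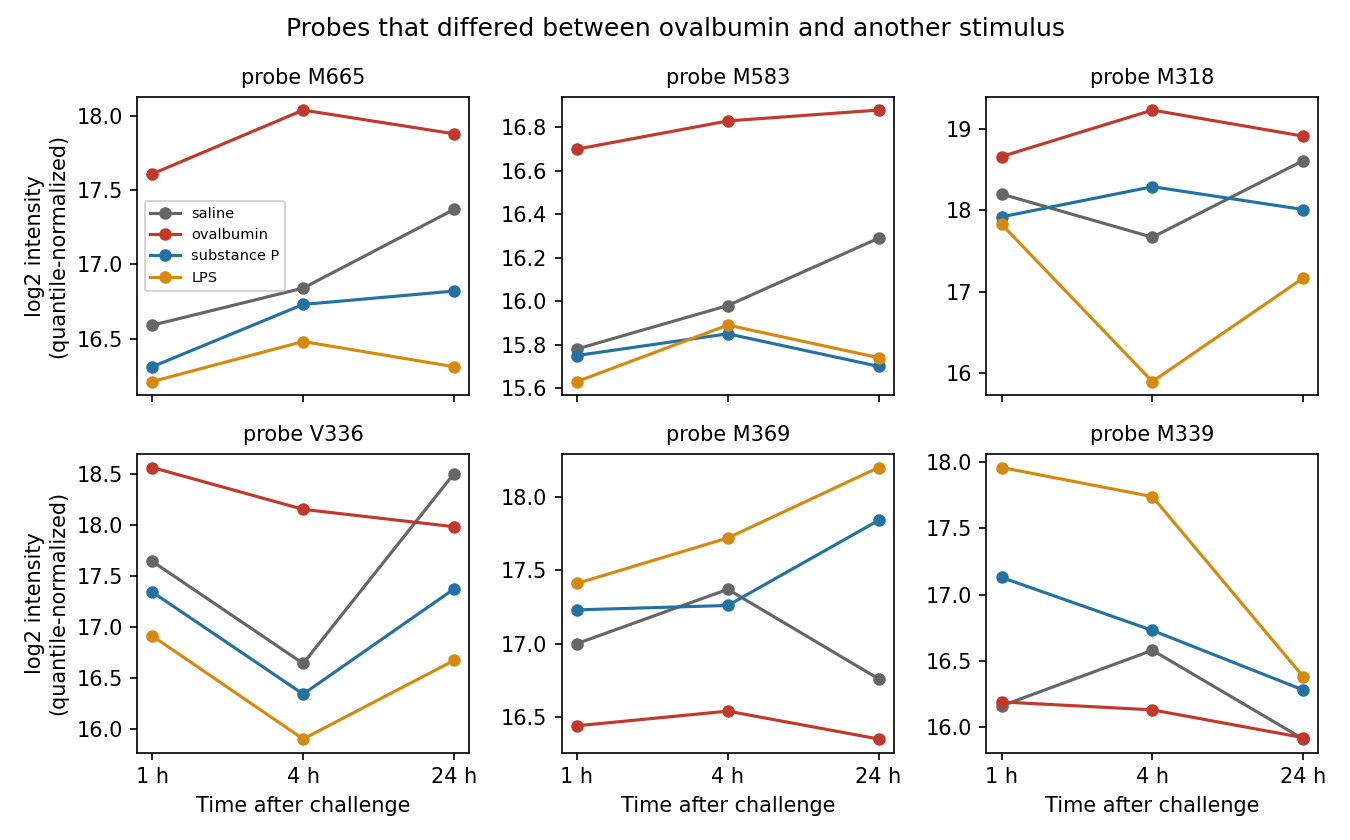
Quantile-normalized log2 intensity of 6 probes at 1, 4 and 24 h for saline, ovalbumin, substance P and LPS; each point is 1 array, lines join the times of a treatment and the vertical scales differ. The ovalbumin points lie above LPS for M318 and V336 and below it for M369 and M339, and the saline 24 h point of V336 (18.50) lies between the ovalbumin points at 1 h and 4 h.

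No probe differed between all 3 stimuli together and saline in limma (40 with an unadjusted p under 0.05). The time course common to the 4 treatments gave 0 probes for 4 h against 1 h and 0 for 24 h against 1 h, with 57 and 65 probes at an unadjusted p under 0.05. Without scaling 3 and 173 probes passed, all lower at the later time. Across probes, the time-averaged log2 ratios of substance P and LPS correlated at r = 0.501, and unchanged groups sharing the saline arrays gave a mean of 0.499 in 1000 simulated sets. Median scaling turned this r to -0.225. The ratios of ovalbumin correlated at -0.243 with those of substance P and at -0.021 with those of LPS, against 0.5 simulated for each. Median scaling gave -0.628 and 0.435. Without the 24 h arrays both were above 0, at 0.139 and 0.21. The covariance differed from its simulated value by -0.0279 and -0.0185 for these pairs, and by 0.00421 for substance P and LPS. The simulated sets drew every array independently, so the shared saline arrays alone put their r near 0.5. These sets do not carry the likeness of saline 24 h to ovalbumin. They are therefore no fair reference for the 2 pairs with ovalbumin, and the gaps draw no conclusion on the responses. With 3 saline arrays the controls could not be split into sets of at least 2.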

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

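Of the tests below, those on the saline 24 h array were chosen after its correlations had been seen; the counts of other splits were planned.

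The difference between 2 stimuli is the difference of their effects against saline, and it passed the limma test for 34 probes between ovalbumin and LPS and for 6 between ovalbumin and substance P. The probes given in the report were higher with ovalbumin than with substance P by 1.22 (M665) and 1.04 (M583) on the log2 scale, and differed from LPS by 1.96 (M318), 1.74 (V336), -1.33 (M369) and -1.28 (M339). Among the 10 ways to split the same 6 arrays 3 against 3, only the real one reached its count (1 of 10 for each), and the highest other split gave 0 probes for both; 10 splits are too few for a share under 0.05. The 3 ovalbumin arrays are the only ones labelled lot 1, and their mice are the only ones labelled as sensitized. No sex is given for these mice, while the other mice are labelled female. The 90th percentile before scaling was 1.32 to 1.59 times the 10th on the ovalbumin arrays and 2.64 to 3.52 times on the substance P arrays. On the LPS arrays it was 2.48, 1.36 and 1.55 times at 1, 4 and 24 h. Lot, sensitization, sex and this range therefore remain untested explanations of these differences beside the challenge.

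Where the real count was 0, every split reaches it by construction, so the number of splits says nothing about chance. These were 10 of 10 for each stimulus against saline and for substance P against LPS, 35 of 35 for 4 h and for 24 h against 1 h, and 100 of 100 drawn for the 3 stimuli together. The highest other split gave 1 probe for ovalbumin, 0 for substance P and 1 for LPS against saline, 1 for substance P against LPS, and 1 and 0 for 4 h and 24 h against 1 h. For the 3 stimuli together, the highest other split gave 43 probes, with ovalbumin 1 h, ovalbumin 4 h and saline 24 h against the other 9 arrays. The next gave 13, with the same ovalbumin arrays and saline 1 h, and 7, with saline, substance P and LPS at 24 h. The highest count points to a structure of the arrays.

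The saline 24 h array correlated more closely with the ovalbumin arrays than with the other saline arrays, and 4 explanations were weighed. Background added evenly to an array cannot change ranks, and the quantile-normalized values follow ranks, so it could not have made this pattern. Over the 590 brighter probes the mean Spearman rho was 0.823 with ovalbumin and 0.538 with saline. The difference was 0.285 (bootstrap 95% interval over probes 0.242 to 0.334), which restates the pattern and tests nothing further. Background that differs between probes was not tested. Saline 24 h also had the narrow range of the ovalbumin arrays. Its 90th percentile was 1.43 times its 10th, against 1.32 to 1.59 times for ovalbumin and 2 and 2.51 times for saline 1 h and 4 h. LPS 4 h and 24 h were as narrow (1.36 and 1.55 times), with r of 0.764 and 0.843 to saline 24 h. A part played by this range was not tested. A swap of labels with an ovalbumin array needs a partner, and 0 of the 3 ovalbumin arrays were closer to saline 1 h and 4 h than to each other. The time of 24 h alone is argued against as the whole cause. The mean r with substance P and LPS at 24 h minus that with ovalbumin at 1 h and 4 h was -0.106 (interval over probes -0.142 to -0.08). Both intervals leave out the spread between arrays, of which each group has 1. A part played by the time stays open, and the values do not decide it. Within substance P and within LPS the 24 h array was the closest to saline 24 h (r = 0.85 and 0.843). These 24 h arrays were also the closest of their treatment to saline 1 h (r = 0.925 and 0.875). Within ovalbumin the 24 h array was the farthest from saline 24 h (r = 0.896, against 0.955 and 0.951 at 1 h and 4 h). An array lot shared with the ovalbumin arrays, or a wrong label with no partner, stays open: 0 lots are given for the saline 24 h array, so these cannot be told apart, and no biological explanation was tested.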

How the results depend on the processing

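With median scaling the model gave 183 probes for ovalbumin against substance P, 0 for ovalbumin against LPS and 33 for substance P against LPS (all higher with substance P). The deposited values shifted the median log2 ratio against saline of the same time by -0.97 to 0.54 and gave 1177, 343 and 437 probes for ovalbumin, substance P and LPS against saline, 1184 for ovalbumin against substance P, 1152 for substance P against LPS, 30 for ovalbumin against LPS (1 higher and 29 lower, 3 shared with the 34), and 3 and 173 for 4 h and 24 h against 1 h. The 2-fold counts at 1, 4 and 24 h under the deposited values were 508, 540 and 45 for ovalbumin, 107, 75 and 208 for substance P, and 265, 93 and 115 for LPS. Median scaling moved them to 15 for ovalbumin at 1 h, 72, 15 and 58 for substance P, and 76 and 19 for LPS at 4 h and 24 h. The normexp correction raised them to 409, 326 and 346, to 355, 123 and 408, and to 397, 407 and 451. V336 for substance P reversed to 0.15 with median scaling and 0.59 without scaling, and without scaling M722 reversed to -0.26, M665 to -1.15 and M583 to -0.72. The reversals of M722, M665 and M583 came where nearly all probes were lower with ovalbumin. Ovalbumin against substance P (6 probes) gave 2 with the 25th percentile floor, 2 with no filter, 29 with a trended robust variance, 1 without the time factor, 201 with array weights and 2 with normexp. Array weights gave 2 for ovalbumin against saline. Apart from these, the counts of the model stayed within 1.5 times under the other planned settings and normexp, and the stimuli against saline also on the brighter probes (both chosen after the data were seen). A similar count did not always mean the same probes. Of the 34 between ovalbumin and LPS, 25 were among the 42 with a trended robust variance and 23 among the 37 with normexp. All 34 were among the 36 with the 5th percentile floor. Leaving out 1 array or 1 time gave ranges of 0 to 27 probes for ovalbumin against saline (27 without saline 24 h, 26 without all 24 h arrays), 0 to 8 for LPS against saline, 0 to 79 for ovalbumin against substance P, 0 to 60 for ovalbumin against LPS and 0 to 12 for substance P against LPS. Both upper ends for ovalbumin against the other stimuli came without saline 24 h (the 60 also without all 24 h arrays), and the last without LPS 24 h. The correlation of ratios was -0.628 for ovalbumin and substance P, 0.435 for ovalbumin and LPS and -0.225 for substance P and LPS with median scaling, and -0.324 for the first pair on probes above the floor on all 12 arrays. Leaving out a time gave -0.141 to 0.139 for the first pair, 0.038 to 0.21 for the second and 0.386 to 0.714 for the third. The cause of these changes was not tested. For the named probes, under median scaling, no scaling, the other floors, normexp and each time left out, 110 values kept direction and side of the threshold, 8 passed it newly, 21 no longer passed and 5 reversed. With each array left out in turn, 174 of 216 values stayed on their side, 2 passed newly and 0 reversed. Of the 72 values of probes that passed with all arrays, 40 no longer passed. The gene list alternatives were not run for lack of gene names. The background under dim probes limits what any of these settings can resolve.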

Other observations

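Apart from the test of the shared saline array, the tests here were chosen after the result was seen. At 1 h, 9 probes were at least 2-fold above saline on both the substance P array (12 such probes) and the LPS array (30), where 0.305 would be shared by independent lists. The 10 probes 2-fold higher with ovalbumin at 1 h shared 0 with either list, where 0.102 and 0.254 would be shared by independent lists, so this 0 does not set ovalbumin apart. The median log2 ratio of the 9 probes was 1.5 for substance P and 2.02 for LPS at 1 h, 0.26 and 0.63 at 4 h, and 0.02 and 0.15 at 24 h. With ovalbumin it was 0.04, -0.36 and -0.11. The 9 were picked on the 1 h arrays, so some decline toward later times is built in. All but V164 also stood higher on saline 4 h than on saline 1 h, so part of the fall by 4 h comes from the control. Probe M493 was higher at 4 h than at 1 h, with substance P (17.98 against 17.46) and with LPS (18.2 against 17.37). M295 and V005 were at the floor on saline 1 h, so their 1 h ratios are lower bounds. Probe M781 is the plainest case: it stood at 20.14 on the log2 scale on both 1 h arrays and between 15.90 and 16.90 on the 3 saline arrays and the 3 ovalbumin arrays. The equal 20.14 shows an equal rank on the 2 arrays after quantile normalization, not an equal measured level. Averaged over times, its log2 difference from saline was 1.92 for substance P and 1.10 for LPS under median scaling. Without scaling it was 2.36 and 0.52.

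Both lists share the saline 1 h array, which could alone make them overlap. When one ratio used saline 1 h and the other saline 4 h, 6 probes were shared in either arrangement. This is above the upper point of 1 that the hypergeometric distribution gives for independent lists, and argues against the 1 shared saline array as the whole cause. That point takes every probe as equally likely to reach 2-fold, so it is too low if some probes vary more than others. Both saline arrays are labelled lot 2 (r = 0.907), and anything they have in common was not tested. With median scaling the 2 arrangements shared 9 and 8 probes (0.797 and 1.40 expected), and without scaling 5 and 3 (0.325 and 0.361). After normexp correction they shared 30 and 28, where 14.3 and 28.5 would be expected, so there the excess was seen in 1 arrangement only. A common early response of the bladder to the neuropeptide and to LPS is a hypothesis for these probes. It rests on 1 array each, and the genes behind the codes are not known here. The ovalbumin arrays differ in lot from the other arrays whose lot is given, and only their mice are labelled as sensitized.

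Each array was also set against every saline array. The ovalbumin arrays at 1, 4 and 24 h had 2, 0 and 9 probes 2-fold apart from saline 24 h, 36, 32 and 46 from saline 4 h, and 23, 25 and 36 from saline 1 h. The substance P arrays had 49, 30 and 31 from saline 24 h, 6, 4 and 2 from saline 4 h, and 14, 14 and 6 from saline 1 h. The LPS arrays had 56, 59 and 33 from saline 24 h, 29, 26 and 13 from saline 4 h, and 33, 51 and 25 from saline 1 h.

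Probe V128 was chosen after its values were seen. It stood at 16.83 on saline 24 h and at 16.91, 16.99 and 16.97 on the ovalbumin arrays, and between 17.49 and 19.13 on the other 8.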
